A study of Mus musculus with 2 samples.

How the data were processed

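Sorted live intestinal immune cells from irradiated mice (10 Gy of X-rays) were measured in 2 single-cell RNA libraries, 1 labelled WT and 1 labelled Dpf2 KO. Cells had been digested from intestine, stained with a viability dye and sorted by FACS with gates on GFP and tdTomato, per the labels. The labels do not give the time after irradiation, the number or sex of the mice, or the deleted part of Dpf2. The deposited files hold raw counts, meaning UMI counts per gene and cell barcode made with Cell Ranger 7.0.0 per the file headers, on genome build GRCm38 per the submitters' processing notes. The annotation release and the inclusion of intronic reads are not given in the sources used here. Of 54838 gene IDs, 54723 (99.8%) were in the GENCODE annotation used here for gene positions and spans.

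The WT file held 10958 barcodes with 64786549 UMIs and the KO file 8794 barcodes with 49590755 UMIs. Cells with fewer than 200 genes or 500 UMIs (5 in WT and 34 in KO) or more than 20% mitochondrial UMIs (61 and 113) were left out, which kept 10896 and 8681. Scrublet in scanpy 1.11.5, run per library with its default settings, called 607 (5.57%) and 460 (5.30%) of these as doublets, which were left out too. Kept cells had 57681363 UMIs in WT and 44637234 in KO. In WT the 5th and 95th percentiles of UMIs per cell were 1121 and 13126, and in KO 1159 and 13637.

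Both libraries were clustered together without batch correction, since genotype and library are the same split. Counts were scaled to 10000 per cell and logged, 2000 variable genes were chosen by dispersion within 20 bins of mean expression (immunoglobulin and T cell receptor segments left out), and 30 principal components were linked to 20 nearest neighbours by shared neighbours and clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. T cells were clustered again in the same way for subsets. Marker genes of 31 cell types and subsets were fixed before the data were examined. The rule that turned markers into names was written after the clusters had been seen. A cluster took a type's name if at least 3 of its markers were among the 100 genes with the highest fold over other cells (of genes in at least 25% of its cells) and at least 3 were found in 10% or more of its cells, if no other type had more markers among its 10 leading genes or had markers among its first 5 where the type itself had none, and by the highest scaled mean expression where more than 1 type passed. Clusters with a median depth at least 3 times lower than that of all cells also needed a marker among the 10 leading genes. Monocyte and macrophage clusters were joined in 1 class, as were the dendritic cell types other than plasmacytoid ones and the stromal types. Clusters without a name made up 4.47% in WT and 6.17% in KO.

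Gene levels were UMIs summed over the cells of a class per 1000000 UMIs of that class. The log2 ratio was taken of KO over WT after adding 10 per 1000000 to each. A gene was eligible in a class with 100 or more UMIs over both libraries and a UMI in at least 5% of the class's cells in at least 1 library. Classes with at least 100 cells in each library were compared. Because each genotype has 1 library, no test was run and cells were not used as replicates. Levels carry exact Poisson intervals, fold differences conditional binomial intervals, and shares exact Clopper-Pearson intervals, with share ratios bounded by the opposite ends of the 2 share intervals. Intervals of list medians came from 500 Poisson draws of the counts. Shares of cells with a UMI were counted after thinning every cell to 1000 UMIs. Cells were called in cycle with at least 2 UMIs of the cell cycle list, and plasma cells were assigned to the heavy chain with the most UMIs if it had at least 10. Cells were also split by Xist and by the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, a split chosen after the data had been seen.

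The 36 gene lists were fixed in advance, and a list was placed in a class where at least 3 members were eligible. Protein folding genes here are the ER stress and unfolded protein response list. It also holds stress sensors and factors such as Ern1, Atf4 and Ddit3. Each list median was placed among 10000 random lists of eligible genes of the same size, drawn within 100 ranks of each member's mean expression, and called apart below the 2.5th or above the 97.5th percentile. A percentile describes these libraries and is not a p-value. A second set of random lists, added after a trend with gene length was seen, was also matched on gene span in 5 groups of equal size. Genes were named by a rule fixed in advance: Dpf2, the 10 eligible genes with the highest and the 10 with the lowest log2 ratio in each of the 3 largest compared classes, and 3 each way in the others. Segments, sex-linked, haemoglobin and mitochondrial transcripts, unnamed gene models and markers of other classes were left out of that ranking, and up to 4 of those markers were named apart. A place on another class's marker list does not show that a transcript came from that class, and Ly6c2 in T cells, Ly6d in B cells and Pf4 in monocytes or macrophages are read as transcripts of the class itself. The ranking passed over 1 segment, 5 unnamed models and 6 markers in T cells, 2 segments, 1 unnamed model and 5 markers in B cells, and 7 unnamed models and 14 markers in monocytes or macrophages. From each gene list, 2 to 4 eligible members with the largest absolute log2 ratio were named in classes where the list was apart, and in the largest class otherwise, with fewer where members had been named already or are not reported here. This was narrowed, after the values were seen, to the classes whose list median is printed, and the plot of list medians shows the rest. Counts of genes at least 2-fold apart describe size only.

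Plasma cell medians are given relative to the class median of -0.14, and TMM factors from edgeR 4.0.16 in R 4.3.3 for this class were 1.08 for WT and 0.929 for KO. Alternatives tried were other cell filters (10% mitochondrial UMIs, 500 genes and 1000 UMIs, doublets kept), resolutions 0.5 and 2, each library clustered alone, clustering without genes at least 2-fold apart, TMM scaling, totals without immunoglobulin, haemoglobin, mitochondrial and ribosomal protein genes, means over cells, thinning to 1000 or 2000 UMIs, 1 or 50 per 1000000 added before the logarithm, no expression filter or one of 500 UMIs, clusters weighted alike (those with at least 10 cells in each library), and cells of 1 sex. The last split, the equal weighting, the clustering without differing genes and the count of cluster 15 as B cells were added after the data had been seen.

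The comparison was tested on simulated data in which Poisson counts for both libraries were drawn from the pooled profile of a class and 200 genes were changed by a known factor in 1 of them, so variation between mice is not covered. In T cells (7375 genes), B cells (6777) and monocytes or macrophages (8117), 0% of unchanged genes and 100% of genes raised 4-fold passed 2-fold. Of genes lowered to 0.25 of their level, 84%, 93.3% and 82.2% passed, against 82%, 95.6% and 84.4% expected with the constant added to levels. Of 200 random lists of 20 unchanged genes, each placed among 1000 others, 8%, 6% and 8% fell outside the central range. The lowest coverage of the 95% intervals was 88.9%, in B cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with a fixed seed.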

Results

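Live immune cells sorted from the intestine of mice given 10 Gy of X-rays were profiled in 2 single-cell libraries, 1 from WT mice and 1 from Dpf2 knockout (KO) mice. After filtering, the WT library held 10289 cells with a median of 4543 UMIs and 1883 genes, and the KO library 8221 cells with a median of 4103 UMIs and 1754 genes. With 1 library per genotype, no difference reported here has a replicate check, and every interval covers counting error only. Each is a 95% interval, except that share ratios are bounded by opposite ends of 2 such intervals and so are wider. Gene levels are UMIs per 1000000 UMIs of the class. In brackets after a gene stand the WT level and the KO level, and where given the fold difference with its interval. Cell class names are short for clusters whose leading genes are like that type.

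The summed Dpf2 level was lower in the KO library in every compared class, but the transcript was still detected there. Dpf2 (chromosome 19, 5896516 to 5913010) encodes a PHD-finger subunit of the BAF chromatin remodelling complex. Over all cells its level was 33.3 in WT and 19.6 in KO (ratio 0.589, 0.543 to 0.638). The difference was largest in T cells (39.8 and 17.7, ratio 0.445, 0.367 to 0.535) and conventional dendritic cells (34.2 and 15.6, ratio 0.455, 0.361 to 0.571), followed by group 3 innate lymphoid cells (ILC3; 53.1 and 25.3, ratio 0.477, 0.295 to 0.770), monocytes or macrophages (35.9 and 19.6, ratio 0.547, 0.449 to 0.664) and NK cells (35.5 and 19.9, ratio 0.559, 0.333 to 0.916). It was smaller in plasma cells (18.2 and 12.3, ratio 0.674, 0.50 to 0.896) and B cells (39.8 and 27.2, ratio 0.682, 0.559 to 0.833). Many of these intervals overlapped, and thinning turned round the order of T cells and monocytes or macrophages. In neutrophils (29.7 and 17.3, ratio 0.583, 0.277 to 1.26) and group 2 innate lymphoid cells (ILC2; 26.8 and 15.6, ratio 0.582, 0.229 to 1.38) the interval included 1. With every cell thinned to 1000 UMIs, a Dpf2 UMI was found in 3.36% (3.01 to 3.73) of WT cells and 1.98% (1.69 to 2.32) of KO cells, leaving out 428 and 310 cells below that depth. Without thinning the shares were 15.8% and 9.16%. Thinned shares were close in the 2 libraries in neutrophils (1.88% in WT and 2.13% in KO, 4 and 9 cells) and plasma cells (1.42% and 1.31%, 19 and 8 cells), where few cells held 1 and the interval of each ratio included 1. The lower level fits the genotype labels, but the deleted part of the gene is not given in the sources used here, and a 3' tag outside that part checks nothing.

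**Figure D1:**
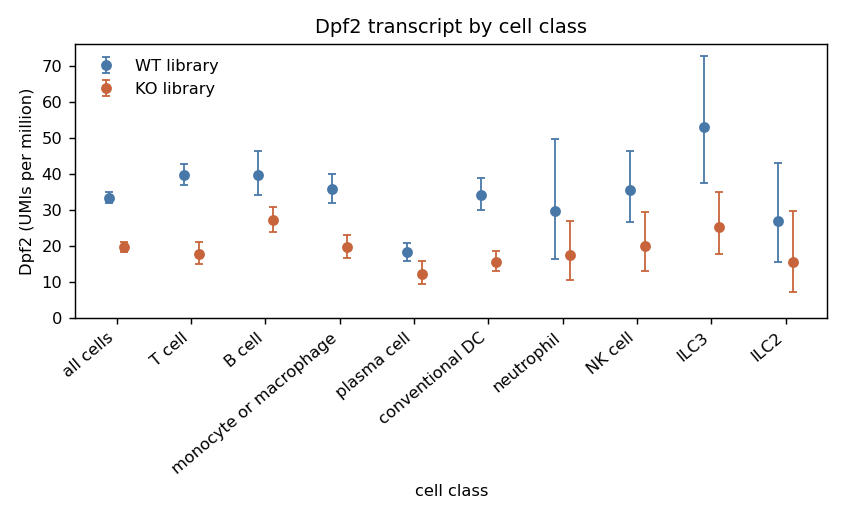
Dpf2 level (UMIs per 1000000) over all cells and in each compared cell class of the WT and KO libraries, with exact Poisson 95% intervals on the counts. The KO value lies below the WT value in each class.

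The mix of immune cells differed between the libraries. B cells, neutrophils and ILC3 made up a larger share of the KO library, and T cells, plasma cells and stromal cells a smaller one. These shares are of cells passing the sort for live immune cells, which was gated on GFP and tdTomato. Which of the gated populations went into each library, and in what proportion, is not given in the sources used here. They describe the sorted suspension and not the tissue. T cells were 36.4% (35.4 to 37.3) in WT and 20.3% (19.4 to 21.1) in KO (KO:WT ratio 0.557, 0.520 to 0.597), and B cells were 10.7% (10.1 to 11.3) in WT and 29.8% (28.8 to 30.8) in KO (ratio 2.79, 2.55 to 3.05). Plasma cells were 13.1% (12.5 to 13.8) in WT and 7.58% (7.02 to 8.17) in KO (ratio 0.577, 0.508 to 0.655). Neutrophils, which enter damaged gut from the blood, were 2.55% (2.25 to 2.87) in WT and 6.19% (5.68 to 6.73) in KO (ratio 2.43, 1.98 to 2.99), and ILC3, the main innate source of IL-22, were 1.22% (1.02 to 1.46) in WT and 3.04% (2.68 to 3.44) in KO (ratio 2.48, 1.84 to 3.36).

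Conventional dendritic cells were 6.43% (5.97 to 6.93) in WT and 7.80% (7.23 to 8.40) in KO (ratio 1.21, 1.04 to 1.41). Monocytes or macrophages were 14.9% (14.3 to 15.7) in WT and 13.3% (12.6 to 14.1) in KO (ratio 0.891, 0.805 to 0.987). NK cells (3.07% in WT and 2.97% in KO, ratio 0.966, 0.763 to 1.22), ILC2 (1.23% in WT and 1.39% in KO, ratio 1.12, 0.781 to 1.61) and plasmacytoid dendritic cells (0.389% in WT and 0.389% in KO) had ratios whose intervals included 1. Stromal cells, which are not immune cells, were 5.52% (5.09 to 5.98) in WT and 1.14% (0.925 to 1.40) in KO (ratio 0.207, 0.155 to 0.275). Unnamed clusters held 4.47% in WT and 6.17% in KO. Within the T cells the largest cluster of the WT library was cluster 3, with 1156 cells against 333 in KO, and the largest of the KO library was cluster 5, with 424 cells against 760 in WT. Within the monocytes or macrophages, the macrophage-like cluster 13 held 95 WT and 228 KO cells and the monocyte-like cluster 1 held 1443 and 867. Some leading genes of these clusters differed between the libraries themselves, such as Ccl5 and Nkg7 in T cells and Stfa2l1 in neutrophils. Clustering without the 512 genes that lay at least 2-fold apart in a class gave ratios of 0.553 for T cells, 2.68 for B cells, 0.583 for plasma cells, 2.44 for neutrophils and 2.57 for ILC3.

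**Figure D2:**
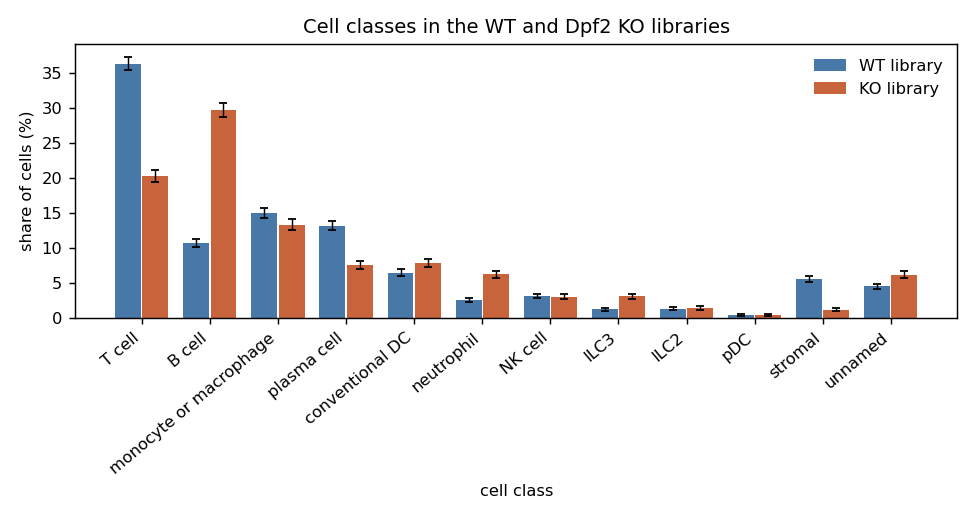
Share of all kept cells (%) in each cell class of the WT and KO libraries, with exact binomial 95% intervals. T cells were the largest class of the WT library and B cells the largest of the KO library.

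Both libraries were mixtures of male and female cells, although the labels give no sex. In WT, 2777 cells held Xist UMIs and no Y-linked UMI and 3639 held Y-linked UMIs and no Xist, and in KO the numbers were 2312 and 2252. Cells with both kinds numbered 891 in WT, where independence within cells would give 1615, and 632 in KO, where it would give 1033. Neutrophils had no such shortfall, with 7 in WT and 17 in KO against 6.39 and 15.5. Stromal cells had 73 and 18 against 67.4 and 14.1, and KO plasma cells 57 against 60.0. In these the split is not shown to part the sexes. Of cells with 1 kind only, 2.51% of WT and 1.89% of KO stromal cells were Xist-only, against 43.3% and 50.7% of all cells. Stromal cells were thus nearly all Y-linked in both libraries, unlike the rest. Contrasts by sex here are therefore contrasts between these cells, not shown to be between female and male mice. The direction of the share ratios held in both sexes for T cells (0.627 in Xist-only cells and 0.464 in Y-linked-only cells), B cells (2.51 and 2.88), plasma cells (0.467 and 0.585), neutrophils (3.0 and 2.96), and ILC3 (2.13 and 2.78). For stromal cells the ratio was 0.217 in Y-linked-only cells, while 10 WT and 1 KO Xist-only cells gave 0.120, 0.00166 to 1.39, an interval that included 1. Monocytes or macrophages had a ratio of 1.34 (1.08 to 1.65) in Xist-only cells, the reverse of the whole library, and 0.969 in Y-linked-only cells.

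Among T cells the KO library had a smaller CD8-like subset and larger Th17-like and naive or central memory-like subsets. The CD8-like subset was 26.3% (24.9 to 27.8) in WT and 16.9% (15.1 to 18.8) in KO (ratio 0.641, 0.544 to 0.753). It joined 2 subclusters that went opposite ways, 1 led by Ly6c2 with 16.2% of WT and 1.92% of KO T cells and 1 led by Cd8a with 10.1% and 15%. Xist-only and Y-linked-only cells went opposite ways. The number and sex of the mice are not given, so sex, single mice and other differences between these cells cannot be told apart. Among Y-linked-only T cells the subset was 45.6% in WT and 10.2% in KO (ratio 0.224, 0.153 to 0.317), while among Xist-only T cells it was 7.20% in WT and 18% in KO (ratio 2.5, 1.75 to 3.57). Naive or central memory-like T cells were 5.35% (4.65 to 6.12) in WT and 18.3% (16.4 to 20.2) in KO (ratio 3.42, 2.69 to 4.35), with ratios of 2.33 in Xist-only and 5.0 in Y-linked-only cells. Th17-like cells were 20.7% (19.4 to 22) in WT and 35.4% (33.1 to 37.7) in KO (ratio 1.71, 1.5 to 1.95), and this ratio turned to 0.772 at the highest clustering resolution and 0.764 with each library clustered alone. Regulatory-like T cells were 6.5% in WT and 7.09% in KO (ratio 1.09, 0.805 to 1.47), and unnamed subclusters held 41.2% in WT and 22.4% in KO. Clustering without the genes at least 2-fold apart gave 0.653 for CD8-like, 1.41 for Th17-like and 3.38 for naive or central memory-like cells.

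Marker UMIs counted without clusters gave the same order for CD8 cells. After thinning to 1000 UMIs, a Cd8a or Cd8b1 UMI was present in 9.93% (8.98 to 10.9) of WT and 4.74% (3.76 to 5.89) of KO T cells. An Il17a or Il17f UMI was present in 8.27% (7.40 to 9.21) and 10.0% (8.62 to 11.6), and a Foxp3 UMI in 1.04% and 0.985%. Plasma cells served as background: Cd8a or Cd8b1 was found in 0.225% of WT plasma cells and in 0 KO plasma cells (upper limit 0.602%). Thinning left out 76 WT and 41 KO T cells and 16 and 12 plasma cells. Median depths before thinning were 4087 and 4144 UMIs in T cells and 8930 and 7687 in plasma cells.

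**Figure D3:**
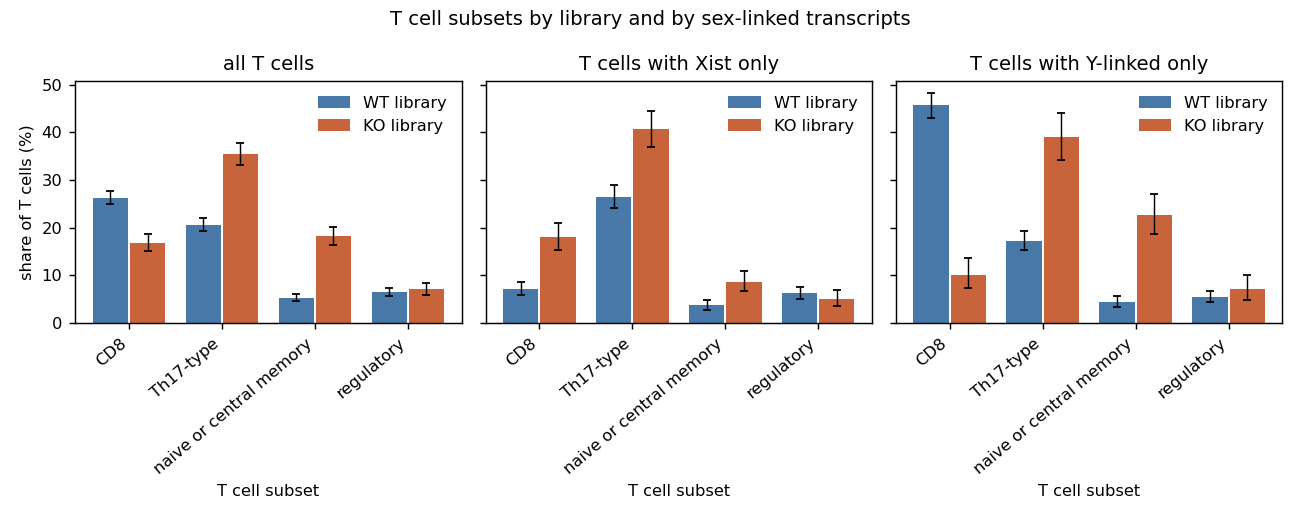
Share of T cells (%) in each T cell subset of the WT and KO libraries, over all T cells, over T cells with Xist and no Y-linked UMI, and over T cells with Y-linked and no Xist UMI, with exact binomial 95% intervals. The CD8 bars change order between the Xist-only and Y-linked-only panels.

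T cells of the KO library held less cytotoxic, cell division and tissue-residency transcript and more heat shock, NF-kB and p53 target transcript. Of 7375 eligible genes, 12 were at least 2-fold higher and 43 at least 2-fold lower in KO, a description of size only. These counts rest on ratios taken after adding 10 per 1000000 to each level, which the folds in brackets leave out, here and in the other classes. With levels averaged over cells the split was 21 and 36. The genes furthest lower were, in order, Gzma (686 and 175, 3.92-fold, 3.71 to 4.15), Pclaf (93.0 and 19.3, 4.82-fold, 4.07 to 5.75), Nkg7 (231 and 59.5, 3.89-fold, 3.53 to 4.29), Lgals1 (298 and 80.0, 3.72-fold, 3.42 to 4.05) and Ccl5 (1336 and 469.6, 2.84-fold, 2.75 to 2.95), then Ube2c (30.0 and 4.82, 6.22-fold, 4.45 to 8.93), Birc5 (31.4 and 5.34, 5.87-fold, 4.27 to 8.28), Pycard (45.4 and 11.7, 3.87-fold, 3.11 to 4.87), S100a10 (429.9 and 164, 2.62-fold, 2.47 to 2.78) and S100a6 (726 and 289, 2.51-fold, 2.40 to 2.63). Gzma encodes a granzyme, Nkg7 a protein of the lytic granule and Ccl5 a chemokine that draws in leukocytes. Pclaf, Ube2c and Birc5 are division genes. Log2 ratios in Xist-only and Y-linked-only cells were -1.84 and -2.21 for Gzma and -1.44 and -2.49 for Nkg7, lower in both, while that of Ccl5 was -0.07 in the first and -2.88 in the second. With clusters weighted alike, Pclaf was at -1.01, against -1.81 as found.

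Heat shock genes led the higher side in T cells, with Hspa1b (151 and 673, 4.47-fold, 4.26 to 4.68), Hspa1a (62.5 and 279, 4.46-fold, 4.15 to 4.80) and Hsph1 (101 and 239.8, 2.38-fold, 2.23 to 2.54). Hspa1a and Hspa1b encode inducible HSP70. Over the compared classes Hspa1a was higher in 9 of 9 and Hspa1b in 8 of 9. With 1 library per genotype, handling of the suspension cannot be told apart from genotype for these genes in any class. Next came Tmem267 (20.2 and 57.2, 2.83-fold, 2.45 to 3.26), Pak1 (123 and 273, 2.21-fold, 2.08 to 2.35), Rn7sk (17.0 and 43.5, 2.56-fold, 2.19 to 3.0), Nfkbid (57.9 and 124, 2.15-fold, 1.96 to 2.35) and Ier5l (24.2 and 57.6, 2.38-fold, 2.08 to 2.72), where Nfkbid encodes a nuclear regulator of NF-kB. Igfbp4, a gene of naive T cells, was also higher (22.3 and 53.4, 2.40-fold, 2.08 to 2.76), but its log2 ratio was -0.22 with clusters weighted alike. Transcripts of other cells in this class were the Paneth cell genes Defa30 (1.51 and 26.6, 17.6-fold, 11.7 to 27.3) and Defa24 (2.91 and 58.2) and the B cell gene Ebf1 (40.1 and 111). Ifitm1 (55.7 and 11.6), on the basophil marker list, and Ly6c2 (69.9 and 19.0), on the monocyte list, were lower, but Ly6c2 also led a CD8-like subcluster and is a T cell transcript here. Positions of the main genes are Gzma (chromosome 13, 113093825 to 113100981), Nkg7 (chromosome 7, 43437073 to 43438249), Ccl5 (chromosome 11, 83525778 to 83530518), Lgals1 (chromosome 15, 78926725 to 78930465), Hspa1b (chromosome 17, 34956436 to 34959238) and Hspa1a (chromosome 17, 34969190 to 34972156).

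The cytotoxic effector list had a median log2 ratio of -0.29 (-0.36 to -0.22) in T cells, with 18 of 20 measured members lower, percentile 0.04 among random lists. Besides Gzma, Nkg7 and Ccl5 it held Gzmb (458 and 207). Random lists matched on gene span as well as expression put it at percentile 4.12. Its median was -0.03 in Xist-only and -0.84 in Y-linked-only cells. With clusters weighted alike it was -0.15, and with the finer T subclusters weighted alike -0.12, with 12 of 20 members lower. Gut homing and residency genes had a median of -0.39 (-0.46 to -0.33), below all 10000 random lists, led by Itgb7 (109 and 52.7) and Cxcr3 (24.4 and 11.1). Itgb7 encodes the integrin chain that pairs with alpha-4 or alpha-E for entry into and retention in the gut wall. MHC class I presentation genes were at -0.39 (-0.44 to -0.33), below all 10000 random lists, with the immunoproteasome genes Psmb8 (83.7 and 36.2), Psmb9 (65.6 and 27.9) and Psmb10 (31.3 and 11.3), and interferon gamma response genes at -0.26 (-0.32 to -0.19), percentile 0.04, although Cxcl10 (69.2 and 119) was higher. Checkpoint and activation genes were at -0.18 (-0.23 to -0.12), percentile 0.49, with Pdcd1 (25.3 and 8.46) and Ctla4 (1105 and 755) lower and Nr4a3 (530.1 and 823) higher.

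Naive and memory genes were higher as a group in T cells (0.28, 0.23 to 0.35, percentile 99.9), with Bcl2 (183 and 303), Satb1 (1152 and 1827) and Lef1 (209.9 and 331). Weighting the T cell clusters alike turned this median to -0.15. NF-kB inflammatory genes had a median of 0.44 (0.34 to 0.47), above all 10000 random lists, with Nfkbia (534 and 1042), Cxcl2 (65.8 and 118) and Nfkb1 (1242 and 1954). p53 targets, which include transcripts induced by DNA damage, were at 0.24 (0.18 to 0.31), percentile 99.98, with Cdkn1a (241 and 417), Plk2 (28.8 and 51.0), Ccng1 (61.3 and 102) and Zmat3 (26.8 and 46.9). The heat shock list was at 0.51 (0.37 to 0.55), above all 10000 random lists, and included Dnajb1 (64.9 and 118). Dissociation and immediate early genes, which handling of tissue also induces, were at 0.42 (0.38 to 0.45), above all 10000 random lists, with Klf4 (135 and 248), Zfp36 (187 and 336) and Fos (327 and 540.3). This list and the p53 targets were both higher in T cells, plasma cells, NK cells and ILC2, and Btg2 is on both. For p53 targets, handling was therefore not set apart from a response to DNA damage. Repair macrophage genes, of which 7 were measured, were at 0.30 (0.12 to 0.38), percentile 99.42, with Il10 (35.6 and 56.1) and Vegfa (8.01 and 14.5). Their median was 0.029 without the expression filter. Hypoxia and glycolysis genes were at -0.14 (-0.18 to -0.10), percentile 0.96, with Gapdh (591 and 366) and Aldoa (91.5 and 56.4), and at percentile 3.83 when span was matched. The sex-linked list was at -0.42 (-0.51 to -0.23), percentile 0.825, with Eif2s3y (42.4 and 22.9) lower and Xist (474 and 549) higher.

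Fewer T cells and plasma cells of the KO library carried cell division transcripts. The S and G2/M list had a median log2 ratio of -0.67 (-0.76 to -0.60) in T cells, with 19 of 21 members lower and Top2a (78.5 and 27.5), below all 10000 random lists. The dividing T cell cluster held 135 WT and 15 KO cells, and with clusters weighted alike the median was -0.39 and Birc5 was at -0.90. At least 2 UMIs of that list, after thinning to 1000 UMIs, were found in 47.3% (45.7 to 49.0) of WT and 38.2% (35.8 to 40.6) of KO T cells, and in 19.7% (17.6 to 21.9) and 11.0% (8.60 to 13.7) of plasma cells. Over all cells the shares were 34.6% and 28.2%. Without thinning they were 91.3% and 87.2% in T cells and 88.5% and 76.6% in plasma cells. Neutrophils, which do not divide, reached 33.3% and 20.9% after thinning, so this measure is not specific to division. A UMI of Mki67 or Top2a was stricter: 5.51% and 2.59% of T cells (ratio 0.469, 0.297 to 0.726), 6.82% and 2.46% of plasma cells (ratio 0.360, 0.166 to 0.727), and 5.33% and 2.04% of monocytes or macrophages (ratio 0.383, 0.195 to 0.722). In conventional dendritic cells it was found in 3.99% and 6.77% (ratio 1.70, 0.854 to 3.44), and in monocytes or macrophages the list median was 0.13 (-0.05 to 0.16), percentile 78, so the list did not follow the stricter measure there.

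B cells of the KO library, a larger share of the sorted cells, differed less in their transcripts. Immunoglobulin, interferon response, antigen presentation and protein folding transcripts were lower, and few genes were higher. Of 6782 eligible genes, 5 were at least 2-fold higher and 14 at least 2-fold lower after the same 10 per 1000000 were added, or 7 and 12 with levels averaged over cells. In the order of those ratios, the higher side named Pbx3 (95.6 and 255, 2.66-fold, 2.40 to 2.97), Dnah17 (35.2 and 92.0, 2.62-fold, 2.20 to 3.14), Hspa1b (329 and 683, 2.07-fold, 1.96 to 2.20), Nr6a1 (105 and 216, 2.06-fold, 1.86 to 2.28) and Gk5 (34.2 and 74.1, 2.17-fold, 1.81 to 2.61), then Zbtb2 (93.0 and 186, 1.99-fold, 1.79 to 2.23), Tnfaip2 (11.7 and 31.2, 2.66-fold, 1.97 to 3.67), Ahcyl2 (413 and 791, 1.92-fold, 1.82 to 2.02), Cpne9 (13.6 and 34.1, 2.51-fold, 1.89 to 3.38) and Fhit (42.7 and 87.9, 2.06-fold, 1.75 to 2.43), of which only the first 3 passed 2-fold that way. Pbx3 encodes a homeodomain transcription factor and Nr6a1 an orphan nuclear receptor. The gene furthest lower was Ly6d (326 and 98.7, 3.30-fold, 3.04 to 3.59), which is on the marker list of plasmacytoid dendritic cells but is a B lineage gene too. The lower side further named Cd52 (505 and 220.4, 2.29-fold, 2.16 to 2.44), Sdf2l1 (22.3 and 5.11, 4.35-fold, 3.05 to 6.30), Vpreb3 (172 and 75.6, 2.28-fold, 2.05 to 2.53), Ly6a (86.9 and 36.3, 2.39-fold, 2.06 to 2.78) and Ccl5 (58.8 and 23.1, 2.54-fold, 2.11 to 3.07), then Camk4 (62.8 and 25.2, 2.49-fold, 2.08 to 2.98), Ppdpf (46.6 and 17.7, 2.64-fold, 2.14 to 3.26), Sh3bgrl3 (217 and 101, 2.14-fold, 1.96 to 2.35), Basp1 (67.5 and 29.2, 2.31-fold, 1.95 to 2.74) and Hist1h1c (148 and 71.5, 2.07-fold, 1.85 to 2.31). Ccl5 in WT B cells was at 4.40% of its WT T cell level, close to Gzma at 3.76%, so its difference here is not set apart from T cell RNA in the suspension. Sdf2l1 encodes a chaperone partner in the endoplasmic reticulum, Vpreb3 a B lineage protein and Ly6a the surface antigen Sca-1. Positions are Pbx3 (chromosome 2, 34171457 to 34373142), Cd52 (chromosome 4, 134082448 to 134095082), Vpreb3 (chromosome 10, 75943057 to 75949657) and Ly6a (chromosome 15, 74994877 to 74998031). On the marker lists of other classes were Mzb1 (147 and 66.8), Gzma (25.8 and 5.54) and Defa24 (1.87 and 23.2).

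Immunoglobulin constant region transcripts had a median of -0.62 (-0.65 to -0.56) in B cells, below all 10000 random lists, with Iglc3 (66.6 and 26.3) and Igkc (4533 and 2238). The plasma cell marker Mzb1 (147 and 66.8, 2.21-fold, 1.97 to 2.47) was lower in this class as well, and RNA of plasma cells, a smaller share of the KO library, was not separated from B cell transcript. Interferon gamma response genes were at -0.35 (-0.45 to -0.28), below all 10000 random lists, with Irf1 (297 and 179) and Gbp2 (17.3 and 7.35), and type I interferon response genes at -0.24 (-0.29 to -0.14), percentile 0.06, with Ly6e (289 and 181) lower and Oasl1 (25.8 and 52.1) higher. That last median was 0.03 when genes with few UMIs were let in. MHC class II presentation genes were at -0.30 (-0.35 to -0.26), percentile 0.03, with H2-DMb2 (225 and 125), H2-Oa (108 and 76.4) and Cd74 (4614 and 3414), and MHC class I genes at -0.32 (-0.40 to -0.25), below all 10000 random lists, with H2-Q7 (141 and 78.3) and Psmb8 (39.8 and 20). Type 3 genes, of which 6 were measured, were at -0.51 (-0.63 to -0.39), below all 10000 random lists, with Ltb (57.9 and 25.8) and Ccr6 (50.2 and 24.6). Ltb encodes lymphotoxin beta and Ccr6 a receptor that guides B cells to gut lymphoid follicles. Protein folding genes were at -0.24 (-0.28 to -0.16), below all 10000 random lists, with Pdia4 (62.1 and 28.4) and Manf (123 and 70.7). Pyroptosis and necroptosis genes were at -0.23 (-0.32 to -0.10), percentile 0.94, with Pycard (19.0 and 9.16) and Casp4 (111 and 74.6). Their median was -0.052 without the expression filter, -0.081 with the filter of 500 UMIs and -0.12 with doublets kept.

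Monocytes or macrophages of the KO library showed opposite differences in the interferon programmes. Type I interferon response genes were higher, while interferon gamma response, MHC, hypoxia and protein folding genes were lower. Of 8139 eligible genes, 45 were at least 2-fold higher and 57 at least 2-fold lower, or 33 and 64 with edgeR TMM scaling. On the higher side stood Tmem267 (643 and 2747, 4.28-fold, 4.15 to 4.40), Ms4a7 (29.8 and 106, 3.56-fold, 3.09 to 4.10), Mreg (8.46 and 41.9, 4.95-fold, 3.84 to 6.46), Blnk (42.5 and 136, 3.20-fold, 2.84 to 3.61) and Arhgap10 (139.5 and 393, 2.82-fold, 2.64 to 3.01), then Apoe (702 and 1866, 2.66-fold, 2.58 to 2.74), Pdxk (53.1 and 151, 2.85-fold, 2.56 to 3.17), Arhgap6 (41.7 and 121, 2.90-fold, 2.57 to 3.28), Pvt1 (34.7 and 103, 2.97-fold, 2.60 to 3.40) and Shtn1 (23.8 and 74.0, 3.11-fold, 2.65 to 3.66). Apoe and Ms4a7 are genes of resident macrophages and are among the leading genes of the macrophage-like cluster, which was larger in KO. With the clusters weighted alike the log2 ratio of Apoe was 0.73, against 1.40 as found, and that of Ms4a7 was 0.54, against 1.54.

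On the lower side in monocytes or macrophages stood Plcb1 (1088 and 197, 5.52-fold, 5.23 to 5.82), Glis3 (203 and 30.9, 6.57-fold, 5.75 to 7.54), Cacna1d (426 and 81.6, 5.22-fold, 4.80 to 5.68), Kctd19 (104 and 19.6, 5.32-fold, 4.48 to 6.34) and Cxcl9 (119 and 24.7, 4.81-fold, 4.13 to 5.62), then Il7r (202 and 51.2, 3.95-fold, 3.54 to 4.41), Slc7a2 (66.3 and 13.6, 4.87-fold, 3.96 to 6.03), Ly6a (83.1 and 21.9, 3.80-fold, 3.22 to 4.51), Nrg1 (87.5 and 23.6, 3.71-fold, 3.16 to 4.37) and Vcan (145 and 48.6, 2.99-fold, 2.67 to 3.36). Plcb1 encodes a phospholipase C, Cacna1d a calcium channel subunit, Cxcl9 a chemokine that draws in CXCR3-bearing T cells, and Vcan a proteoglycan made by monocytes. Positions are Plcb1 (chromosome 2, 134786067 to 135475258), Cxcl9 (chromosome 5, 92321347 to 92328079), Apoe (chromosome 7, 19696109 to 19699188) and Tmem267 (chromosome 13, 119488039 to 119611059). On the marker lists of other classes were Defa24 (2.63 and 38.2), Ccl17 (7.66 and 56.4) and Cadm1 (29.3 and 135). Pf4 (27.2 and 94.9) is on the platelet list but is also among the leading genes of the macrophage-like cluster, and its log2 ratio was 0.72 with clusters weighted alike, against 1.5 as found.

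Type I interferon response genes in monocytes or macrophages had a median of 0.39 (0.34 to 0.44), with 34 of 42 members higher, above all 10000 random lists, and were led by Ifit2 (38.4 and 95.9), Ifit1 (138 and 307), Ifit3 (9.14 and 29.1) and Mx1 (10.5 and 30.0). This median was 0.23 after thinning, 0.25 in Xist-only and 0.20 in Y-linked-only cells. Interferon gamma response genes had a median of -0.33 (-0.40 to -0.26), with 20 of 24 lower, below all 10000 random lists, including Nos2 (21.8 and 4.0), Gbp2 (241 and 121) and Psmb9 (72.0 and 39.1). Nos2 encodes the inducible nitric oxide synthase. MHC class II genes were at -0.33 (-0.43 to -0.24), percentile 0.01, with H2-Eb1 (2393 and 1239) and Cd74 (5078 and 3041), but at 0.04 when called doublets were kept, and MHC class I genes were at -0.41 (-0.44 to -0.33), below all 10000 random lists, with Psmb8 (98.6 and 55.9) and H2-Q7 (138 and 85.4). Hypoxia and glycolysis genes were at -0.36 (-0.40 to -0.29), below all 10000 random lists, with Bnip3 (58.7 and 28.7), Egln3 (33.4 and 15.1), Hif1a (565 and 345) and Slc2a1 (131 and 78.7). Protein folding genes were at -0.28 (-0.34 to -0.23), below all 10000 random lists, with Creld2 (50.2 and 16.2), Sdf2l1 (80.1 and 31.5) and Manf (284 and 148). NRF2 targets were at -0.13 (-0.21 to -0.08), percentile 0.54, with Gstm1 (27.5 and 13) and Gclm (83.3 and 50.6) lower and Osgin1 (9.71 and 20) higher. Pyroptosis and necroptosis genes were at -0.14 (-0.22 to -0.06), percentile 1.28, with Il1b (2389.5 and 1453) lower and Nlrp3 (625 and 795) higher. Dissociation and immediate early genes were at -0.15 (-0.17 to -0.10), percentile 0.42, or 3.04 with span matched, with Atf3 (565 and 299) and Jun (309 and 194).

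Plasma cells of the KO library held less protein folding and cell division transcript and more IgG and IgM heavy chain transcript. The median of all eligible genes in this class was -0.14, so plasma list medians below are relative to that value, while levels in brackets are as measured. Of 8190 eligible genes, 34 were at least 2-fold higher and 63 at least 2-fold lower. The higher side named Terb2 (3.45 and 36.8, 10.7-fold, 7.63 to 15.2), Scin (15.3 and 74.6, 4.87-fold, 4.08 to 5.83) and Hspa1b (84.1 and 308, 3.67-fold, 3.39 to 3.97), with log2 ratios relative to the class median of 1.94, 1.89 and 1.90. The lower side named Manf (694 and 195, 3.56-fold, 3.33 to 3.81), Ube2c (36.2 and 4.75, 7.62-fold, 5.05 to 12.0) and Mki67 (71.4 and 17.0, 4.20-fold, 3.36 to 5.30), at -1.64, -1.5 and -1.45 on the same scale. Manf encodes a protein of the endoplasmic reticulum that is secreted under folding stress (chromosome 9, 106838312 to 106891979). Protein folding genes had a relative median of -0.54 (-0.66 to -0.47), with 20 of 21 lower as measured, below all 10000 random lists. They included Hsp90b1 (3844 and 1429), Creld2 (305 and 109) and Calr (587 and 216). Cell cycle genes were at -0.55 (-0.63 to -0.47), below all 10000 random lists, with Birc5 (29.2 and 5.34) and Top2a (71.6 and 27.7). The dividing plasma cell cluster held 132 WT and 16 KO cells. With the 2 plasma clusters weighted alike, the cell cycle median was -0.21 as measured, against -0.70 as found on that scale. On the same weights Mki67 was at -0.77, Ube2c at -0.92 and Top2a at -0.29 as measured.

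Most plasma cells of both libraries were of the IgA class. Among plasma cells with at least 10 UMIs of their leading heavy chain, Igha led in 98.8% (98.1 to 99.3) of WT and 92.9% (90.6 to 94.8) of KO cells, and Ighg2b in 0.602% (0.260 to 1.18, 8 cells) and 4.29% (2.82 to 6.22, 26 cells). Immunoglobulin constant region transcripts had a relative median of 0.93 (0.91 to 1.06), above all 10000 random lists, with Ighg1 (110.4 and 780.1) and Ighg2b (623 and 3402). As measured, the log2 ratios in Xist-only and Y-linked-only cells were 0.49 and 5.23 for Ighg1 and 1.40 and 6.39 for Ighg2b. NF-kB inflammatory genes were at 0.49 (0.39 to 0.54), above all 10000 random lists, with Tnfaip2 (17.0 and 38.4) and Cxcl2 (75.5 and 136), dissociation and immediate early genes at 0.37 (0.33 to 0.43), above all 10000 random lists, with Junb (302 and 551) and Ier2 (86.6 and 151) higher and Klf2 (316 and 168) lower, and p53 targets at 0.22 (0.14 to 0.29), percentile 99.94, with Mdm2 (358 and 537) and Cdkn1a (58.8 and 88.6). Interferon gamma response genes were at -0.19 (-0.25 to -0.11), percentile 1.34 but 4.31 with span matched, with Iigp1 (15.4 and 3.16) and Psmb8 (88.9 and 44.1). On the marker lists of other classes were Apoe (33.3 and 218), Ly6d (707 and 205) and Dcn (21.2 and 2.18). The epithelial list rested on 3 measured genes and was at 1.24 (0.99 to 1.43), percentile 99.97, from Defa24 (2.48 and 35.8) and Defa30 (1.92 and 15.4).

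Conventional dendritic cells of the KO library held more chemokine, anti-apoptotic and NF-kB transcript. Ccl17 (chromosome 8, 94810453 to 94812036) and Ccl22 (chromosome 8, 94745590 to 94751699) encode chemokines that draw in CCR4-bearing T cells, and Fscn1 an actin bundler of mature dendritic cells. The higher side named Ccl17 (49.2 and 408, 8.29-fold, 7.40 to 9.31), Ccl22 (96.2 and 480.3, 4.99-fold, 4.59 to 5.44) and Fscn1 (9.34 and 68.0, 7.28-fold, 5.59 to 9.61), and the lower side Cd209a (90.1 and 12.0, 7.52-fold, 6.01 to 9.49), Ly6a (87.2 and 15.9, 5.50-fold, 4.51 to 6.75) and Plcb1 (36.8 and 2.53, 14.5-fold, 9.10 to 24.5). Ccl17, Ccl22 and Cd209a are also leading genes of the larger dendritic cell cluster. The class joins dendritic cell types, so a different mix of types inside that cluster was not set apart from a change within cells. Of 8438 eligible genes, 59 were at least 2-fold higher and 36 at least 2-fold lower. Chemokines had a median of 0.37 (0.31 to 0.44), percentile 99.99, with Cxcl16 (173 and 392) higher and Cxcl9 (215 and 87.4) lower. The chemokine median was 0.038 when genes with few UMIs were let in. Anti-apoptotic regulators were at 0.52 (0.38 to 0.58), percentile 99.99, with Bcl2a1a (52.9 and 158), Bcl2a1b (288 and 631) and Bcl2l1 (52.5 and 109.9). NF-kB inflammatory genes were at 0.36 (0.27 to 0.44), above all 10000 random lists, with Il12b (43.6 and 115), Tnfaip2 (222 and 482) and Tnf (45.8 and 94.6), and B cell activation genes, a list that includes costimulatory genes, at 0.20 (0.16 to 0.32), percentile 99.43, with Cd40 (65.4 and 113) and Prdm1 (56.2 and 90.9). Type I interferon response genes were at 0.33 (0.26 to 0.38), above all 10000 random lists, with Ifit1 (42.1 and 158), Rsad2 (106 and 341) and Oasl1 (212 and 515), whereas interferon gamma response genes were at -0.45 (-0.52 to -0.36), below all 10000 random lists, with Gbp7 (34.5 and 16.4) and Gbp2 (96.2 and 53.6). Protein folding genes were at -0.37 (-0.44 to -0.29), below all 10000 random lists, with Creld2 (80.5 and 23.6) and Sdf2l1 (134 and 55.6). Antimicrobial granule genes were at 0.22 (0.12 to 0.27), percentile 98.1, but at 0.068 in Xist-only cells, 0.0033 in Y-linked-only cells and 0.031 after thinning. They included S100a9 (5.63 and 20.4) and S100a8 (4.45 and 15.2), which are neutrophil markers, and Ncf1 (69.5 and 123). Also on the marker lists of other classes were Defa24 (2.08 and 30.8), Ly6d (40.2 and 8.53) and Themis (40.2 and 8.53).

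Neutrophils of the KO library held more stefin A and mitochondrial transcript, at a low depth of 1473.5 and 1735 median UMIs. The stefin A genes encode inhibitors of cysteine proteases and mark mature neutrophils. Stfa2 had 2 UMIs in WT and 656 in KO (141-fold, 38.8 to 1165, chromosome 16, 36403992 to 36408457). It was followed by Stfa1 (19.1 and 435, 22.8-fold, 11.9 to 50.1) and Stfa2l1 (149 and 1809.5, 12.2-fold, 9.60 to 15.7). On the lower side stood Rgs1 (513 and 140.3, 3.66-fold, 2.98 to 4.51), Dach1 (259 and 75.6, 3.42-fold, 2.57 to 4.58) and Upp1 (303 and 91.1, 3.33-fold, 2.56 to 4.34), of which Rgs1 had log2 ratios of -0.80 and -0.89 and Dach1 of -0.62 and 0.26 in Xist-only and Y-linked-only cells, against -1.80 and -1.65 as found. Of 2329 eligible genes, 105 were at least 2-fold higher and 50 at least 2-fold lower. Mitochondrially encoded genes had a median of 1.07 (0.97 to 1.23), above all 10000 random lists, with mt-Atp6 (29.7 and 120.3) and mt-Nd1 (469 and 1276). Hypoxia and glycolysis genes were at 0.27 (0.14 to 0.41), percentile 98.6, with Pgam1 (93.4 and 198) and Hk1 (123 and 226). Of the cytotoxic effector list 4 genes were measured, at -0.67 (-0.85 to -0.57), percentile 0.97, with Ccl4 (3533 and 1281) and Ccl3 (2903 and 1345), while the chemokine list itself stayed within the range of random lists. Dissociation and immediate early genes were at -0.28 (-0.35 to -0.18), percentile 0.74 but 7.34 with span matched, with Rhob (431 and 161) and Jun (1118 and 456). On the marker lists of other classes were Defa24 (14.9 and 110.2), Apoe (44.6 and 199), Cx3cr1 (65.8 and 144) and Wdfy4 (65.8 and 131), and the log2 ratio of Apoe was -0.60 in Xist-only cells.

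NK cells of the KO library, like the T cells, held less cytotoxic and more heat shock and p53 target transcript. The higher side named Tmem267 (24.1 and 81.1, 3.36-fold, 2.28 to 5.06), Hspa1a (188 and 513, 2.72-fold, 2.36 to 3.14) and Cxcl10 (75.8 and 206, 2.72-fold, 2.17 to 3.42) and the lower side Klrc3 (75.8 and 24.7, 3.07-fold, 2.05 to 4.73), Tspo (109 and 39.0, 2.81-fold, 2.03 to 3.94) and Nkg7 (525 and 191, 2.75-fold, 2.38 to 3.19). In Xist-only cells the log2 ratio of Hspa1a was 0.66, that of Hspa1b 0.28 and that of Tmem267 0.53, and that of Klrc3 was -2.5. Of 4035 eligible genes, 12 were at least 2-fold higher and 23 at least 2-fold lower. The cytotoxic effector list had a median of -0.41 (-0.51 to -0.28), with 16 of 19 members lower, below all 10000 random lists, including Eomes (176 and 77.2) and Prf1 (175 and 102). Eomes encodes the transcription factor of mature NK cells and Prf1 perforin. Naive and memory genes, a list that was higher in T cells, were at -0.40 (-0.54 to -0.31), percentile 0.04, with Klf2 (253 and 119) and Foxp1 (1419 and 935). Heat shock genes were at 0.48 (0.36 to 0.67), above all 10000 random lists, with Hspa1b (544 and 1196) and Hsph1 (148 and 327), p53 targets at 0.30 (0.22 to 0.48), percentile 99.77, with Ccng1 (53.7 and 102) and Cdkn1a (229 and 392), and pro-apoptotic regulators at 0.36 (0.08 to 0.47), percentile 99.63, with Bbc3 (34.2 and 66.0). The pro-apoptotic median was 0.012 in Y-linked-only cells and 0.013 without the expression filter. Dissociation and immediate early genes, which handling also induces, were at 0.22 (0.14 to 0.29), percentile 99.93, with Zfp36 (357 and 579) and Cebpb (186 and 278). Gut homing genes were at -0.26 (-0.42 to -0.02), percentile 0.265, with Itgb7 (80.5 and 39.0). Chemokines were at -0.51 (-0.55 to -0.39), percentile 0.05, although Cxcl10 was higher, but at 0.0037 with few-UMI genes let in. Ccl3 (221 and 146), Ccl4 (843 and 583) and Ccl5 (2832 and 1967) are on the cytotoxic list too, so both results overlap. Named from marker lists of other classes were Ebf1 (46.3 and 172), Cd28 (649 and 314), Ms4a4b (102 and 52.5) and Areg (26.8 and 51.7).

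ILC3 of the KO library, although a larger share of the cells, held less interferon gamma response, MHC class II and chemokine transcript. The higher side named Lgmn (22.4 and 65.0, 2.91-fold, 1.70 to 5.29), Cdk14 (88.0 and 234, 2.66-fold, 2.03 to 3.53) and Errfi1 (68.5 and 157, 2.29-fold, 1.67 to 3.18) and the lower side Iigp1 (268 and 44.5, 6.03-fold, 4.53 to 8.12), Gzmc (169 and 38.3, 4.41-fold, 3.19 to 6.17) and Ly6a (271 and 61.6, 4.40-fold, 3.41 to 5.72), of which Errfi1 had a log2 ratio of 0.16 and Gzmc of 0.42 in Xist-only cells. Of 3499 eligible genes, 13 were at least 2-fold higher and 21 at least 2-fold lower. Interferon gamma response genes had a median of -0.69 (-0.96 to -0.51), below all 10000 random lists, with Cxcl9 (264 and 73.9) and Irf1 (446 and 202). Chemokines were at -0.88 (-1.03 to -0.68), below all 10000 random lists, with Ccl5 (123 and 34.2) and Cxcl10 (620.4 and 309.9), and MHC class II genes at -0.84 (-0.98 to -0.62), below all 10000 random lists, with Cd74 (1189 and 593) and H2-Eb1 (474 and 250.4). The chemokine median was -0.01 when genes with few UMIs were let in. Genes of the type I interferon response were at -0.33 (-0.54 to -0.14), percentile 0.745, with Ly6e (722 and 445) and Bst2 (162 and 99.9), or at -0.082 without the expression filter. The type 3 list, the defining programme of these cells, was at -0.30 (-0.45 to -0.09), percentile 0.23, with Ltb (161 and 67.0) and Il17a (229 and 119) lower and Il17f (88.0 and 169.6) higher. Heat shock genes were at 0.53 (0.34 to 0.64), above all 10000 random lists, with Hspa1a (1056 and 2105) and Hspa1b (2813 and 5258). Named from marker lists of other classes were Cd3e (78.3 and 30.1), Ret (32.1 and 69.8), Cd28 (92.2 and 47.2) and Jchain (886 and 1407). The log2 ratio of Jchain was -0.19 with levels averaged over cells, that of Cd3e 0.0049 after thinning and that of Cd28 0.10 in Y-linked-only cells.

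ILC2 of the KO library shared the heat shock and p53 differences and held less type I interferon response transcript, a list measured here by 3 genes. The higher side named Arhgap6 (7.89 and 192, 24.4-fold, 10.1 to 76.6), Hspa1a (63.1 and 335, 5.30-fold, 3.76 to 7.65) and Hspa1b (267 and 1186, 4.45-fold, 3.75 to 5.30) and the lower side Ly6a (167 and 45.1, 3.71-fold, 2.40 to 5.94), Ifih1 (178 and 52.0, 3.43-fold, 2.27 to 5.31) and Slc9a9 (194 and 60.7, 3.20-fold, 2.18 to 4.80), and Arhgap6 had a log2 ratio of 0.28 when called doublets were kept. Of 2205 eligible genes, 31 were at least 2-fold higher and 20 at least 2-fold lower. Heat shock genes had a median of 0.67 (0.49 to 0.86), above all 10000 random lists, with Hsph1 (117 and 298). p53 targets were at 0.48 (0.30 to 0.68), percentile 99.27, with Cdkn1a (382 and 761) and Btg2 (431 and 615), and dissociation and immediate early genes at 0.22 (0.09 to 0.29), percentile 98.9, with Cebpb (155 and 284) and Dusp1 (782 and 1289.7). Genes of the type I interferon response were at -0.86 (-1.16 to -0.57), percentile 0.13, with Ifih1 and Ly6e (427 and 231), or at -0.19 without the expression filter. Gut homing genes were at -0.37 (-0.61 to -0.17), percentile 0.48, with Selplg (115 and 55.5) and Cxcr6 (174 and 98.8), and hypoxia and glycolysis genes at -0.46 (-0.70 to -0.22), percentile 0.36, with Ldha (269.7 and 139) and Pfkp (164 and 83.2). The gut homing median was -0.045 in Xist-only cells, and the hypoxia median -0.0029 without the expression filter. On the marker lists of other classes were Hdc (12.6 and 231), Ebf1 (41.0 and 179), Cd28 (166 and 72.8) and Gzma (345 and 175), but in Y-linked-only cells the log2 ratio of Cd28 was 0.76 and that of Ebf1 0.40.

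Several gene groups differed the same way in many classes. Nuclear-encoded oxidative phosphorylation genes were lower in all 9 compared classes, with medians of -0.49 (-0.56 to -0.47) in T cells, -0.29 (-0.33 to -0.25) in B cells, -0.30 (-0.36 to -0.27) relative to the class in plasma cells and -0.29 (-0.38 to -0.22) in NK cells. In those classes the list stayed outside random lists matched on gene span too, at percentiles of 0, 0.01, 1.8 and 0.17. In the other 5 it did not, with percentiles under that match of 24.6 in monocytes or macrophages, 17.5 in conventional dendritic cells, 10.5 in neutrophils, 3.09 in ILC3 and 5.34 in ILC2. Genes included Atp5j (112 and 58.0), Cox5a (219 and 118) and Ndufa4 (254 and 139) in T cells, Ndufa13 (49.4 and 22.2) and Cox8a (218 and 128) in B cells, Ndufa4 (467 and 204) and Cycs (171 and 77.7) in plasma cells and Uqcr10 (87.9 and 44.5) and Ndufa7 (61.0 and 30.2) in NK cells. In monocytes or macrophages the median was -0.06 (-0.08 to -0.01), percentile 1.08, with Uqcrb (91.9 and 59.4) and Cycs (162 and 114). Mitochondrially encoded transcripts went the other way, at 0.25 (0.21 to 0.29) in T cells, 0.21 (0.16 to 0.26) in B cells and 0.40 (0.25 to 0.45) in NK cells, of which the last was -0.04 in Xist-only cells, with mt-Nd1 (1505 and 2124) and mt-Nd3 (118 and 169) in T cells, mt-Nd3 (129.6 and 215) and mt-Nd1 (1846 and 2577) in B cells and mt-Nd3 (111 and 185) and mt-Co2 (47.6 and 79.5) in NK cells. The median mitochondrial share of a cell's UMIs was 1.68% in WT and 2.03% in KO. Cytosolic ribosomal protein genes had a median of -0.23 (-0.24 to -0.20) in B cells, below all 10000 random lists, or 2.04 with span matched, with Rps7 (1451 and 929) and Rpl15 (416 and 269.6).

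Short genes tended to be lower in KO. In T cells the median log2 ratio was -0.13 in the fifth of genes with the shortest span (up to 8.87 kb) and 0.08 in the fifth with the longest (from 77.5 kb). Of 294 pairs of a list and a class, 121 lay outside the central range of random lists matched on expression, and 99 of these stayed outside when span was matched. MHC class I presentation kept its place in 6 of 8 classes, interferon gamma response in 5 of 6, protein folding in 4 of 6 and cytotoxic effector genes in 4 of 7.

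Genes of the BAF complex, the complex that holds DPF2, stayed within the central range of random lists in every compared class. In T cells their median was -0.03 (-0.08 to 0.02), with 11 of 22 measured members higher and 11, Dpf2 among them, lower, percentile 33.2, and apart from Dpf2 the largest differences were Bcl7c (26.7 and 16.8) and Smarca2 (169.7 and 228). In NK cells 13 of 13 measured members were higher, with a median of 0.19 (0.06 to 0.29), percentile 95.4. Lists for DNA damage repair, ferroptosis, type 2 genes and TGF-beta and immunosuppression also stayed within that range in the classes where they had enough genes, which were 5 classes for DNA damage repair and 5 for type 2 genes. In T cells DNA damage repair genes were at -0.09 (-0.15 to -0.01), percentile 18.9, with H2afx (39.7 and 21.6) and Brca1 (31.9 and 18), and ferroptosis regulators at 0.09 (-0.06 to 0.16), percentile 81.7, with Ncoa4 (40.4 and 60.4) and Gpx4 (82.0 and 63.4). Type 2 genes were at -0.01 (-0.09 to 0.08), percentile 52.9, with Ptger2 (16 and 11.6) and Areg (64.9 and 53.5), and TGF-beta and immunosuppression genes at 0.06 (0.02 to 0.15), percentile 68.9, with Tgfbr1 (97.0 and 141) and Lgals1 (298 and 80.0). Haemoglobin transcripts had no eligible member.

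**Figure D4:**
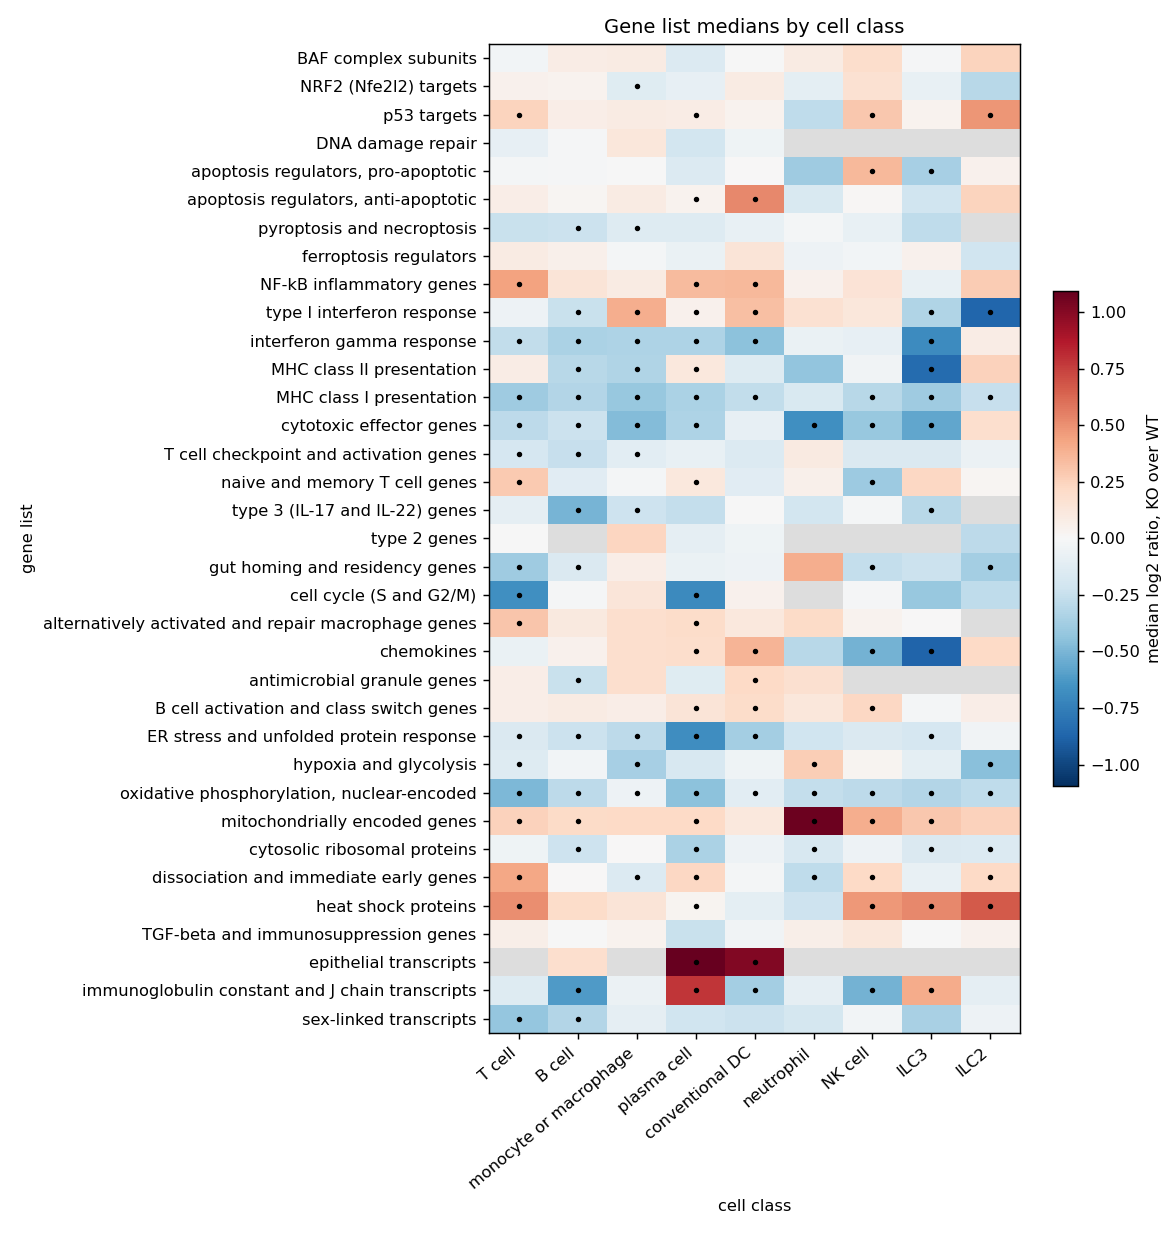
Median log2 ratio (KO over WT) of each gene list in each compared cell class, as measured, with a dot where the median lay outside the central 95% of 10000 random lists matched on mean expression and grey where fewer than the needed genes were measured. Nuclear-encoded oxidative phosphorylation genes were dotted in all 9 classes.

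RNA of epithelial cells was found in every class. Paneth cell transcripts were more abundant in the KO library, where Defa24 ranged from 23.2 to 110.2 UMIs per 1000000 over the compared classes, against 1.58 to 14.9 in WT. T cell effector transcripts appeared in B cells of the WT library at a few percent of their T cell level, such as Nkg7 at 4.35% and Gzmb at 2.76%.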

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

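All tests of explanations in this part were written only after the result they bear on had been seen.

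Some gene lists lay outside random lists in opposite directions in different cell classes. This difference between classes was not itself tested, and some of it depended on the settings given in brackets. Type I interferon response genes were higher in KO monocytes or macrophages (median log2 ratio 0.39) and lower in KO B cells (-0.24, but 0.030 without the expression filter), in ILC3 (-0.33) and, by 3 measured genes, in ILC2 (-0.86). Naive and memory T cell genes were higher in T cells (0.28, but -0.15 with clusters weighted alike) and lower in NK cells (-0.40). Chemokines were higher in conventional dendritic cells (0.37) and lower in ILC3 (-0.88) and NK cells (-0.51). Without the expression filter the medians were 0.038, -0.014 and 0.0037 in that order. Hypoxia and glycolysis genes were higher in neutrophils (0.27) and lower in T cells (-0.14, at percentile 3.83 with gene span matched). Dissociation and immediate early genes were higher in T cells (0.42) and lower in monocytes or macrophages (-0.15, at percentile 3.04 with span matched). Immunoglobulin constant and J chain transcripts were higher in plasma cells (0.78 as measured) and lower in B cells (-0.62).

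The CD8-like share of T cells had a KO:WT ratio of 2.5 among Xist-only cells and 0.224 among Y-linked-only cells. This difference between Xist-only and Y-linked-only cells was not tested, and the number of mice behind each group is not known. The 3 unnamed clusters met the naming rule for none of the marker sets and were compared in no class. Cluster 9 held 4.13% of WT cells, with a median of 1078 UMIs and 8.39% mitochondrial UMIs. Cluster 15 held 3.10% of KO cells and 1 WT cell, and its leading genes mixed the Paneth cell genes Defa24, Defa30 and Lyz1 with the B cell genes Ebf1 and Pax5. Cluster 24 held 0.330% of WT cells and 0 KO cells, led by Igkv17-121 and Mrc1.

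Lower cytotoxic transcript in KO T cells may come in part from cells of 1 sex only. Among Xist-only T cells the cytotoxic list was at percentile 29.5 of random lists, inside their central range, as this explanation predicts. Among Y-linked-only cells it was at percentile 0. But Gzma (-1.84), Nkg7 (-1.44) and Gzmb (-0.68) were lower in Xist-only cells too. The CD8-like share rose in Xist-only cells (KO:WT ratio 2.5) and fell in Y-linked-only cells (0.224). Subsets were not weighted alike within these groups. The test therefore cannot part a change within cells of 1 sex from these opposite shares. A different mix of T cell clusters accounted for part of the size and not for the place: with subclusters weighted alike the median was -0.12, against -0.29 as found, at percentile 1.39, and with clusters weighted alike the percentile was 0.58. Gene length also fits, because random lists matched on gene span put the list at percentile 4.12, against 0.04 without that match. A loss of DPF2 that lowers effector genes in T cells of 1 sex, or in 1 mouse of a pool, was not tested and stays open.

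Lower nuclear-encoded oxidative phosphorylation transcript, seen in all 9 compared classes and in 4 of them outside random lists matched on span, could reflect gene length. In T cells span in 5 groups did not account for it, since the list stayed at percentile 0 of random lists matched that way. In monocytes or macrophages the percentile was 24.6 with the match and 1.08 without. The match used genomic span, so length within a group and the length of the message were left unmatched and stay open. A general loss of short cytosolic messages would lower ribosomal protein transcript as much: the ribosomal protein median was 9.72% of the oxidative phosphorylation median in T cells (-0.05), which speaks against it there, and 78.5% in B cells (-0.23), which fits. The mix of T cell clusters did not account for it, with a median of -0.37 when clusters were weighted alike and -0.33 for subclusters. An effect of the genotype on mitochondrial gene expression was not tested.

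Lower protein folding transcript in KO plasma cells was not explained by the technical tests run. Immunoglobulin transcripts could take up more of the counts, but with those and other abundant genes out of the total the median was -0.61, where the median of all genes was -0.04. Without the dividing cluster it was -0.64 and among Igha-led cells -0.70, at percentiles of 0 and 0. So neither fewer cells of the dividing cluster nor another mix of antibody classes accounts for it. Plasmablasts outside that cluster were not tested. Genotype stays an untested explanation. An earlier choice of a cell cycle pattern and a test of free RNA were replaced by these patterns after results had been seen.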

How the results depend on the processing

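The splits by sex, the equal weighting of clusters, the clustering without differing genes and the count of cluster 15 as B cells were chosen only after results had been seen. No paired analysis was possible because each group has 1 library and both are replicate 1. An alternative kept a result if its value stayed inside the counting interval, or within 1.5-fold for counts of genes. Of 286 alternative values for 29 shares, levels and counts, 223 kept the result, 59 moved it and 4 reversed it. For the 80 list medians printed, 789 of 1044 kept, 250 moved and 5 reversed, and for 315 named genes 2925 of 3643 kept, 706 moved and 12 reversed. Over all lists and genes that the rules name, 31 of 1566 list values and 32 of 6602 gene values were reversed. NK cells took no name in the KO library clustered alone, so no value is given there.

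The T cell share ratio moved to 0.615 with each library clustered alone, 0.627 in Xist-only and 0.464 in Y-linked-only cells. In Xist-only cells the ratio was 2.51 for B cells, 0.467 for plasma cells, 1.47 for conventional dendritic cells, 3.0 for neutrophils and 0.120 for stromal cells, and for monocytes or macrophages it reversed to 1.34. Counting cluster 15 as B cells gave 3.08. The CD8-like ratio reversed to 2.5 in Xist-only cells and was 0.224 in Y-linked-only cells. The Th17-like ratio was 1.33 at resolution 0.5, 1.41 without differing genes and 2.26 in Y-linked-only cells, and reversed to 0.772 at resolution 2 and 0.764 with each library alone. The naive or central memory-like ratio was 2.33 and 5.0 by sex. For each of these the cause was not tested.

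The ratio of cells in cycle depended on the threshold, as counting more or fewer UMIs selects other cells. Over all cells it was 0.957 at 1 UMI, 0.643 at 3 UMIs, 0.519 with Mki67 or Top2a, 0.953 without thinning, 0.925 at 2000 UMIs and 0.752 in Xist-only cells. In T cells it was 0.930, 0.659, 0.469 and, without thinning, 0.956. In plasma cells it was 0.824, 0.294, 0.360, 0.866 without thinning and 0.339 in Xist-only cells. The Dpf2 ratio stayed below 1 over all cells and in the 3 largest classes, at 0.639 in Xist-only cells, 0.633 in thinned T cells, 0.568 in Y-linked-only T cells and 0.363 in thinned monocytes or macrophages. Beyond the thresholds, the cause was not tested.

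Counts of genes at least 2-fold apart followed the constant added before the logarithm, which sets how far weak genes can go. With 1 per 1000000 added, 59 genes were higher and 117 lower in T cells, 26 and 57 in B cells and 154 and 125 in monocytes or macrophages, and with 50 added there were 4 and 12 in T cells, 1 and 3 in B cells, and 7 and 14 in monocytes or macrophages. Higher genes in T cells numbered 21 with means over cells, 24 in Xist-only and 31 in Y-linked-only cells, and lower genes 86 in Y-linked-only cells and 18 with clusters weighted alike. In B cells 9 and 15 genes were higher by sex, 32 lower with doublets kept, and 3 higher and 9 lower with the filter of 500 UMIs, which tests fewer genes. In monocytes or macrophages 37 were lower after thinning, 36 lower with 500 UMIs and 25 higher with clusters weighted alike. For sex, weighting and doublets the cause was not tested.

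The cytotoxic list in T cells had a median of -0.39 with means over cells, -0.50 after thinning, -0.029 in Xist-only and -0.84 in Y-linked-only cells, -0.15 with clusters weighted alike, and -0.40 and -0.16 with 1 and 50 per 1000000 added. Type I interferon response in monocytes or macrophages was 0.33 with TMM, 0.23 after thinning, 0.25 and 0.20 by sex, and 0.49 and 0.23 with 1 and 50 per 1000000. Interferon gamma response there was -0.41 with TMM, -0.41 with clusters weighted alike, -0.23 with 50 per 1000000 and -0.24 without the expression filter. Protein folding in plasma cells, as measured, was -0.54 with TMM, -0.61 with abundant genes out of the total and -0.49 with 50 per 1000000. All 4 kept their sign, and the cause was not tested.

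Reversed list medians were type I interferon response in B cells without the expression filter (0.030), MHC class II in monocytes or macrophages with doublets kept (0.043), naive and memory genes in T cells with clusters weighted alike (-0.15), mitochondrially encoded genes in Xist-only NK cells (-0.041) and chemokines in NK cells without the expression filter (0.0037). Reversed genes were Igfbp4 (-0.22) and Lef1 (-0.16) in T cells with clusters weighted alike, Areg (0.37) in Y-linked-only T cells, and Dach1 (0.26) in Y-linked-only and Apoe (-0.60) in Xist-only neutrophils. In ILC3 they were Gzmc (0.42) in Xist-only cells, Cd28 (0.10) in Y-linked-only cells, Cd3e after thinning (0.0049), and Jchain with means over cells (-0.19), after thinning (-0.31) and in Xist-only cells (-0.68), and in ILC2 Cd28 (0.76) in Y-linked-only cells. For settings other than that filter the cause was not tested. Depth limits the neutrophils most among compared classes, with median UMIs of 1473.5 in WT and 1735 in KO.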

Other observations

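No test was run for the values in this part, which were picked out after the results had been seen. Genes of the Ly6 family on chromosome 15 were lower in KO in several classes. Ly6d had a median log2 ratio of -1.44 over the 5 classes where it was eligible and was at least 2-fold lower in 5. Ly6a was at -1.55, lower in 7 of 7 classes, Ly6e at -0.63, lower in 9 of 9, and Ly6c2 at -1.14 over 4. Ly6a and Ly6e respond to interferon and Ly6d marks B lineage cells.

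Tmem267 on chromosome 13 was at least 2-fold higher in 6 of 8 classes, with a median log2 ratio of 1.20. The genes beside it were less far apart: Paip1 was at 0.08, Nim1k at 0.19, Zfp131 at 0.07 and Hmgcs1 at 0.41. Beside Dpf2 on chromosome 19, Frmd8 was at -0.06 and Capn1 at -0.24. Sdf2l1, which encodes a cofactor of the chaperone BiP, was at least 2-fold lower in 5 of 5 classes.

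Of the Paneth cell transcripts in the compared classes of the KO library, Defa30 was at 0.354 to 0.654 and Lyz1 at 0.146 to 0.232 of the level of Defa24.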
